A study of Mus musculus with 10 samples.

How the data were processed

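Total RNA from cultured murine leukemia stem cell lines was extracted with Trizol and an RNeasy kit, labelled with biotin and hybridised to 10 Affymetrix Mouse Genome 430 2.0 arrays, 1 array per sample. The cells grew in Opti-MEM with fetal bovine serum and stem cell factor. The samples form 4 groups. These are 4 untreated RH-RAS lines, 2 arrays of RH-RAS lines 1 and 3 grown with 1 µM SGC0946 for 4 days, 1 MLL-AF9 line and 3 NUP98-JARID1A lines. Any vehicle in the untreated cultures and the scan dates are not given in the sources used here, so no batch could be assigned.

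The deposited values are log2 intensities per probe set, made by the authors with RMA, which corrects background, normalises quantiles and summarises the probes of each probe set. The version of RMA and the software that ran it are not given in the sources used here. The scale was checked on the values. Array minima lay between 2.21 and 2.34, medians between 5.72 and 5.82 and maxima between 14.7 and 14.8. The sorted columns of the 10 arrays differed by at most 0.163, and probe sets were not centred. No further normalisation was applied. RMA gives no detection calls and compresses low intensities, so a fold change that starts or ends near the bottom of the range is understated. The number of arrays limits the precision of every value.

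Each array held 45101 probe sets, 64 of them Affymetrix controls. The annotation supplied with the array listed 35890, of which 34958 had 1 gene symbol and 932 had several, and 9211 were not listed. Of the probe sets with 1 symbol, 99.4% had an Entrez identifier found in the mouse RefSeq gene table of assembly GRCm38.p6, which was used for names only. No genome build is named for the values and no coordinates are printed. Each of 18194 genes was represented by its probe set with the highest mean over the 10 arrays, and 9012 genes had a choice to make, among at most 12 probe sets. A gene was tested if that probe set lay above the array median on at least 2 of the 10 arrays, which left 11993 genes.

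Fits used limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjusted p over the genes tested and a threshold of 0.05. The effect of SGC0946 was taken from a fit of all 10 arrays with 5 coefficients, as treated lines 1 and 3 minus untreated lines 1 and 3, so that it is the mean of the changes within both lines. Untreated lines 2 and 4 had their own coefficient and entered only the estimate of the spread, as did the NUP98-JARID1A lines. A gene that varied among NUP98-JARID1A lines or between lines 2 and 4 therefore has a larger SE here, even where lines 1 and 3 changed alike. NUP98-JARID1A lines were set against the 4 untreated RH-RAS lines in a fit of the 8 arrays without inhibitor, where MLL-AF9 had its own coefficient. The single MLL-AF9 array has no replicate and was not tested. Its genes were counted where they differed from the RH-RAS mean by at least 2 on the log2 scale and lay outside the range of the 4 RH-RAS lines. The labels call the RH-RAS lines independently derived. They do not say this of the other lines, for which p-values measure only the spread between these samples.

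In both fits, 24 gene lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry. The lists were the Hoxa cluster, the Hoxb cluster, Hox cofactors and MLL-type target genes, stem and progenitor cell genes, primary granule genes, late neutrophil genes, monocyte and macrophage genes, dendritic cell and MHC class II genes, mast cell and basophil genes, erythroid genes, megakaryocyte genes, B lymphoid genes, T and NK lymphoid genes, fibroblast and stromal genes, RAS-MAPK feedback genes, proliferation genes, MYC and ribosome biogenesis genes, p53 targets and cell cycle inhibitors, interferon-stimulated genes, cholesterol biosynthesis genes, amino acid and unfolded protein stress genes, the DOT1L complex and its partners, DNA methylation enzymes, and inflammatory cytokine and NF-kB genes. Members of a list counted as risen or fallen when their adjusted p over all 11993 genes passed, and the counts were repeated with p adjusted over the list alone. For single arrays, the median difference over a list was ranked among 10000 random lists matched on mean expression in 20 bins.

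Genes were named by a rule. It took the 8 largest positive and 8 largest negative log2 fold changes among genes past the threshold that moved the same way in both treated lines or whose groups did not overlap, and the 2 to 4 members of each list with the largest absolute change. For MLL-AF9 it took the 6 genes furthest above and the 6 furthest below the RH-RAS mean. Hoxa5, Hoxa7, Hoxa9, Hoxa10, Meis1, Pbx3, Mn1, Mycn, Flt3 and Dot1l were always named. The always-named genes and the Hoxa and Hox cofactor lists came from prior knowledge of related RH-RAS cells, so their direction is not independent evidence. The comparisons, tests, threshold, lists, naming rule and most alternatives were fixed before the data were examined. The alternatives were other scalings (cyclic loess, median subtraction), other filters, the mean of a gene's probe sets, a mean-variance trend, arrayWeights, the line as a fixed or a random block, other choices of control arrays, other thresholds, other list tests and leaving out each array in turn. Taking untreated line 4 alone as the control, and median subtraction for MLL-AF9 and for the correlation between lines 1 and 3, were added after the data were seen. With the line as a fixed block, the spread came from the NUP98-JARID1A lines and from the difference between the responses of lines 1 and 3. A gene that missed the threshold there need not have responded differently in lines 1 and 3.

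The fits were tested on simulated data with 11993 genes, 200 of them changed. In the simulated SGC0946 comparison, log2 changes of 0.5, 1, 2 and 3 were called with the right sign for 16, 72, 98 and 94% of changed genes, and 6.04% of calls were unchanged genes. For NUP98-JARID1A against RH-RAS the shares were 34, 82, 98 and 98%, and 6.02% of calls were unchanged genes. The simulated noise was independent between genes and had 1 size per gene on every array. In the real data 1 gene was apart by more than 1 between the treated arrays, and 515 to 725 between NUP98-JARID1A lines. The simulated shares therefore check the code and do not give the power or error rate in these data.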

Results

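Expression was measured in lines of mouse leukemia stem cells grown in culture. RH-RAS lines were transformed by the R882H mutant of the DNA methyltransferase DNMT3A together with the G12D mutant of NRAS, and 4 independently derived lines were profiled without treatment. Lines 1 and 3 were also profiled after 4 days with 1 µM SGC0946, a small molecule that inhibits the histone H3 lysine methyltransferase Dot1l. For reference the series holds 1 line transformed by the fusion gene MLL-AF9 and 3 lines transformed by NUP98-JARID1A. Each of the 10 samples has 1 array of 45101 probe sets, on which 11993 genes were tested, and the number of arrays limits the precision.

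The first comparison asks what inhibition of Dot1l did to gene expression in RH-RAS lines 1 and 3. Genes of monocytes and macrophages rose together, and 17 of the 20 measured members rose while the other 3 did not pass the test. Adjusted over the list alone, 19 rose. The mannose receptor Mrc1 rose by 5.10 ± 0.69 on the log2 scale (SE, n = 2 treated and 2 untreated arrays; limma adjusted p = 0.00648), and Csf1r, the receptor for macrophage colony-stimulating factor, by 4.90 ± 0.67, or 29.9-fold (adjusted p = 0.00669). The endotoxin co-receptor Cd14 rose 31.9-fold (SE 1.09 on the log2 scale, adjusted p = 0.0275), and Lyz2, a lysozyme of myeloid cells, by 4.68 ± 0.41 (adjusted p = 0.00293). The median change of the list was 2.90 (camera adjusted p = 3.4e-15), with an adjusted p = 0.278 with an estimated correlation. Untreated line 4 stood apart in this list, with a median 0.98 above lines 1 to 3, at the 100th percentile of 10000 matched random lists. Without the line 4 array 18 members rose, and with the line as a block 16 did. Line 4 enters only the estimate of the spread, so leaving it out does not alter the changes.

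**Figure D1:**
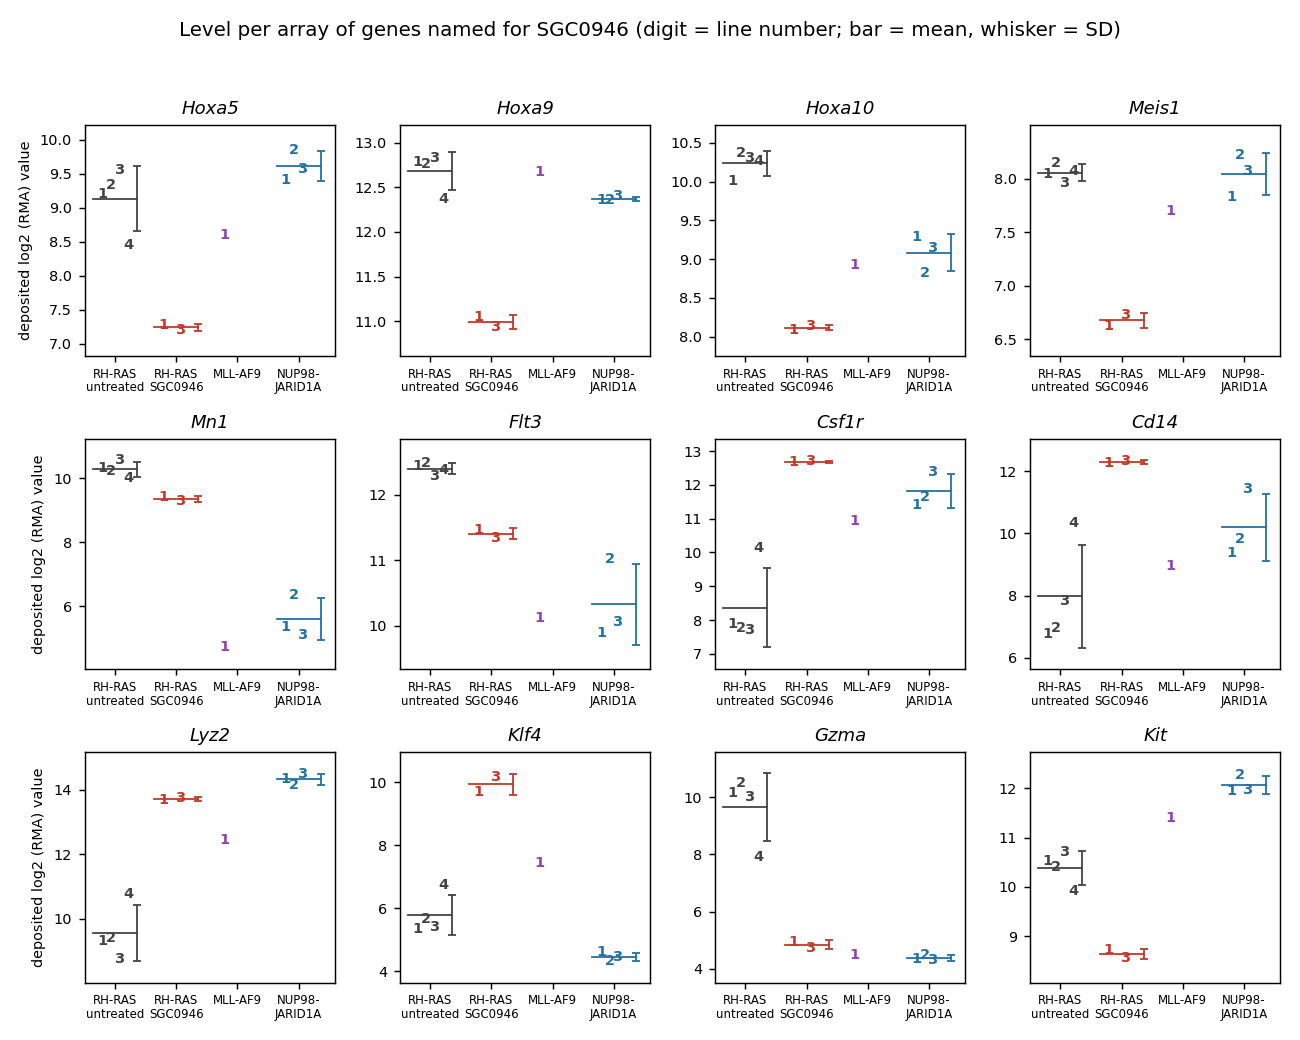
Log2 RMA intensity (vertical axis) of 12 genes on each array, for RH-RAS lines without and with SGC0946, MLL-AF9 and NUP98-JARID1A lines. The single MLL-AF9 array has no bar or whisker. Digits are line numbers, bars are group means and whiskers are SD; Csf1r lay between 7.7 and 7.9 in untreated lines 1 to 3, at 10.1 in untreated line 4 and at a mean of 12.7 in the treated arrays.

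Homeobox genes of the Hoxa cluster, which sustain self-renewal of blood progenitors, fell. Of 7 measured members, 3 fell and 4 did not pass, and 4 fell when adjusted over the list alone. Hoxa5 fell by 2.13 ± 0.28 on the log2 scale (adjusted p = 0.00618), Hoxa10 by 2.04 ± 0.17 (adjusted p = 0.00293) and Hoxa9 by 1.82 ± 0.13, or 3.52-fold (adjusted p = 0.00156). Hoxa7 was lower by −0.55 ± 0.16 and did not pass (adjusted p = 0.0640). The median of the list was −0.55 (camera adjusted p = 0.000114), with an adjusted p = 0.210 with an estimated correlation. In untreated line 4 the median of the Hoxa list was −0.19 from lines 1 to 3, at the 1.57th percentile of random lists. Hoxb genes had a median of 0.06 (camera adjusted p = 0.954), and the 3 measured, Hoxb3, Hoxb4 and Hoxb5, did not pass (−0.18 ± 0.46, 0.06 ± 0.21 and 0.21 ± 0.69). Hoxb5 lay below the array median on every RH-RAS array, treated or not, and was tested because of its level in other lines. Its value says little about a response.

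Among 19 measured Hox cofactors and MLL-type target genes, 5 fell, 2 rose and 12 did not pass. Adjusted over the list alone 9 fell and 2 rose, and with the line as a block 4 fell and 2 rose. The Hox cofactor Meis1 fell by 1.33 ± 0.13 (adjusted p = 0.00354) and the transcription factor gene Sox4 by 1.12 ± 0.12 (adjusted p = 0.00380). Zeb2 and Lmo2, both regulators of blood cell fate, rose by 2.08 ± 0.47 and 1.30 ± 0.27 (adjusted p = 0.0315 and 0.0236). The list median was −0.52 (camera adjusted p = 0.00103), with an adjusted p = 0.278 with an estimated correlation. Mn1 at −1.08 ± 0.36 (adjusted p = 0.105), the receptor kinase gene Flt3 at −0.96 ± 0.33 (0.112), Pbx3 at 0.10 ± 0.73 and Dot1l itself at 0.06 ± 0.14 (0.843) did not pass. In lines 1 and 3 the changes were −0.88 and −1.28 for Mn1 and −0.98 and −0.95 for Flt3. Their SE includes the spread among NUP98-JARID1A lines (SD 0.66 and 0.61), as does that of Pbx3 (SD 1.39). Pbx3, Six4, Eya1 and Mecom, none of which passed, lay below the array median on every RH-RAS array, treated or not. These genes say little about a response. The probe set used for Mycn was at −0.52 ± 0.23 (adjusted p = 0.205), and its other probe sets were at −5.64 ± 1.12 and −2.24 ± 0.35. The always-named genes and both lists were chosen from prior knowledge of related RH-RAS cells, so their direction is not independent evidence.

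Genes of T and NK cells fell, with 4 of 10 past the test and 6 not, and 5 past it when adjusted over the list alone. The cytotoxic protease Gzma fell by 5.25 ± 0.68, or 37.9-fold (adjusted p = 0.00610), the T cell receptor subunit Cd3g by 4.19 ± 0.66 (adjusted p = 0.0110) and the transcription factor Gata3 was at −2.33 ± 0.23 (adjusted p = 0.00350). The list median was −0.70 (camera adjusted p = 7.8e-04; adjusted p = 0.428 with an estimated correlation), and line 4 was at −0.50 from lines 1 to 3, at the 0.01th percentile of random lists. Cholesterol biosynthesis genes had a median of −0.42 (camera adjusted p = 0.000114; adjusted p = 0.505 with an estimated correlation; 0.116 by fry). Of 16 members 2 fell, the synthesis enzymes Lss (−1.18 ± 0.24) and Nsdhl (−0.56 ± 0.15; adjusted p = 0.04996, and 0.0638 with the line as a block), and 14 did not pass, while 4 fell when adjusted over the list alone. Line 4 differed from lines 1 to 3 by −0.40 in this list, and with line 4 alone as the control the list median was −0.07 and the call was lost (adjusted p = 0.242).

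Interferon-stimulated genes had a median of 0.69 (camera adjusted p = 0.000114; adjusted p = 0.505 with an estimated correlation; 0.0932 by fry). Of 20 members 3 rose, among them the RNA sensor Ifih1 by 1.97 ± 0.29 (adjusted p = 0.00860), and 17 did not pass, while 10 rose when adjusted over the list alone. Ifi27l2a was at 3.40 ± 0.91 and did not pass (adjusted p = 0.0520). Dendritic cell and MHC class II genes had a median of 0.61 (camera adjusted p = 0.0125; adjusted p = 0.428 with an estimated correlation). Here 3 of 11 rose and 8 did not pass, against 6 risen and 1 fallen when adjusted over the list alone. The maturation marker Cd83 rose by 3.53 ± 0.45, and H2-DMa and Cd74, which load MHC class II with peptide, by 1.91 ± 0.25 and 1.54 ± 0.20 (adjusted p = 0.00610, 0.00610 and 0.00595). Line 4 lay on the other side of lines 1 to 3 in this list, at −0.39.

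Of 5 erythroid genes, carbonic anhydrase Car2 (−1.80 ± 0.31) and the transferrin receptor Tfrc (−1.22 ± 0.19) fell and 3 did not pass, with the same counts when adjusted over the list alone. The erythroid median was −0.18 (camera adjusted p = 0.0443; 0.0529 with the line as a block; adjusted p = 0.351 with an estimated correlation). In the DOT1L complex and its partners 3 of 13 fell and 10 did not pass, again with the same counts when adjusted over the list alone. These were Mllt3, a reader of acylated histones (−2.69 ± 0.51, adjusted p = 0.0177), the elongation factor gene Aff3 (−2.36 ± 0.46, adjusted p = 0.0198) and Mllt10 (−0.46 ± 0.10, adjusted p = 0.0306), and all 3 missed the threshold with the line as a block (adjusted p = 0.0572, 0.0560 and 0.0790). Lines 1 and 3 nevertheless changed alike, at −2.69 and −2.70 for Mllt3, −2.29 and −2.42 for Aff3 and −0.47 and −0.45 for Mllt10. The spread among NUP98-JARID1A lines enters the block fit too. The list median was −0.21 (camera adjusted p = 0.0439; 0.0644 with the line as a block; 0.0551 without untreated line 4; adjusted p = 0.428 with an estimated correlation), and line 4 was at −0.14 from lines 1 to 3.

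The other lists were not called by camera. Among 18 stem and progenitor genes, 5 fell, 1 rose and 12 did not pass (5 and 2 when adjusted over the list alone, 4 and 1 with the line as a block; median −0.23, camera adjusted p = 0.0543; 0.0249 by fry). Angpt1 fell by 3.12 ± 0.37, the stem cell factor receptor Kit by 1.98 ± 0.19 and the progenitor surface marker Cd34 by 1.67 ± 0.17. In the late neutrophil list 5 of 17 rose and 12 did not pass, alike when adjusted over the list alone, and 2 rose with the line as a block (median 0.17, camera adjusted p = 0.0961). Of those that did not pass, Ltf, Ngp, Camp, Lcn2, S100a8, S100a9, Cd177, Chil3, Padi4 and Stfa2l1 lay below the array median on every RH-RAS array, treated or not. They were tested because of their levels in the other lines, so they say little about a response. The collagenase Mmp8 rose by 2.49 ± 0.34 and the integrin Itgam 4.58-fold (SE 0.33 on the log2 scale). Among 12 primary granule genes the protease Prtn3 (2.09 ± 0.33) and its activating enzyme Ctsc (1.31 ± 0.12) rose, 1 fell and 9 did not pass. Against this, 3 rose and 3 fell when adjusted over the list alone, and 3 rose and 0 fell with the line as a block (median 0.37, camera adjusted p = 0.574). Line 4 was above lines 1 to 3 by 0.28 in the primary granule list and 0.22 in the late neutrophil list.

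In 8 mast cell and basophil genes 2 rose, 2 fell and 4 did not pass, alike when adjusted over the list alone, and 1 rose and 1 fell with the line as a block, with Cpa3 at −2.24 ± 0.52 (adjusted p = 0.0345, and 0.0623 with the block) and Mitf at 1.63 ± 0.32 (median −0.36, camera adjusted p = 0.699). Among 9 B lymphoid genes 3 fell, 1 rose and 5 did not pass, alike when adjusted over the list alone, and 2 fell and 1 rose with the line as a block (median −0.08, camera adjusted p = 0.123). The DNA polymerase Dntt and the recombinase Rag1, both of V(D)J joining, fell 11.3-fold and 5.32-fold (SE 0.36 and 0.23 on the log2 scale). Of 10 megakaryocyte genes the thrombin receptor F2r fell by 2.18 ± 0.24 and 9 did not pass, alike when adjusted over the list alone (median 0.13, mean −0.08, camera adjusted p = 0.837). The 5 fibroblast and stromal genes did not pass (median −0.05, camera adjusted p = 0.831), with Fn1 at 0.27 ± 0.73 and Pdgfrb at −0.26 ± 0.44. Pdgfrb lay below the array median on every RH-RAS array, so it says little about a response.

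Among 19 RAS-MAPK feedback genes 4 fell, 1 rose and 14 did not pass, against 6 and 3 when adjusted over the list alone, and 1 fell and 1 rose with the line as a block (median −0.16, camera adjusted p = 0.243). The immediate early genes Egr1 and Fos moved apart, at −2.45 ± 0.48 (adjusted p = 0.0562 with the line as a block) and 2.30 ± 0.19. Of 25 proliferation genes 1 rose, the survival and mitosis gene Birc5 (0.51 ± 0.13, adjusted p = 0.0412; 0.105 with the line as a block), and 24 did not pass, Tyms among them at −0.31 ± 0.19 (median 0.05, and below 0 after median subtraction; camera adjusted p = 0.699). Of 20 MYC and ribosome biogenesis genes the polyamine enzyme Odc1 fell by 0.40 ± 0.09 (adjusted p = 0.0346, and 0.0918 with the line as a block) and 19 did not pass, with Wdr12 at −0.27 ± 0.12 (median −0.03, camera adjusted p = 0.313). Neither list had a member past the test when adjusted over the list alone. The stress gene Gadd45a fell by 1.64 ± 0.21 and the p53 antagonist Mdm2 also fell, while the other 15 p53 targets and cell cycle inhibitors did not pass, alike when adjusted over the list alone (median −0.04, mean 0.01, camera adjusted p = 0.699).

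In the amino acid and unfolded protein stress list Atf3 rose by 1.75 ± 0.40 (adjusted p = 0.0323), Ddit4 fell by 1.19 ± 0.21, 1 more fell and 14 did not pass, alike when adjusted over the list alone. With the line as a block Atf3 no longer passed (adjusted p = 0.102) and 1 member fell (list median −0.08, camera adjusted p = 0.522). Line 4 was 0.25 above lines 1 to 3 in that list. Of 11 DNA methylation enzymes and partners 1 rose, the methyl-DNA binding gene Mbd2 (adjusted p = 0.0300, and 0.0858 with the line as a block), and 10 did not pass, alike when adjusted over the list alone (median 0.14, mean −0.13, camera adjusted p = 0.750). Dnmt3b was at −1.45 ± 0.51 (adjusted p = 0.117). Among 16 inflammatory cytokine and NF-kB genes the chemokine Ccl9 rose by 3.46 ± 0.46, the NF-kB inhibitor Tnfaip3 fell by 0.70 ± 0.16 and 14 did not pass, alike when adjusted over the list alone (median 0.23, camera adjusted p = 0.588).

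Across all genes, limma called 1434 of 11993, of which 820 rose and 614 fell. At least 2-fold changes numbered 391 up and 249 down. The largest rise was that of Ms4a6d, a membrane protein gene, at 5.56 ± 0.71 or 47.2-fold (adjusted p = 0.00595). It was followed by P2ry6 (5.39 ± 0.65), Mrc1, Dab2 (5.03 ± 0.80), Tgfbi (5.02 ± 0.79), Cd14, Csf1r and the interferon-induced membrane protein gene Ifitm3 (4.81 ± 0.38). The largest falls after Gzma were those of the adenylate kinase gene Ak4 (−4.73 ± 0.57), the cell adhesion gene Cdh1 (−4.70 ± 0.74), Cd3g, Selenbp1 (−4.10 ± 0.60), Stc2 (−4.09 ± 0.58), Gimap9 (−3.58 ± 0.75) and the neurotrophic factor receptor gene Gfra1 (−3.57 ± 0.22). The 5 probe sets of Ak4 ranged from −5.05 to −0.04. All 16 of these genes had an adjusted p of at most 0.0275, and Gimap9 alone missed the threshold with the line as a block (adjusted p = 0.0789). The untreated means of Ifitm3 (4.45) and Mrc1 (4.51) were near background. So were the treated means of Cd3g (4.32), Gimap9 (4.41), Cdh1 (4.54) and Gzma (4.84). The changes of these genes are understated, and the order of the 16 genes is not exact.

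With the line as a block, 844 genes were called (463 higher, 381 lower), and 794 of them were among the 1434. In the main fit untreated line 4 enters only the estimate of the spread, so leaving it out does not alter the changes. Without untreated line 4 the count was 1482, with 1286 shared, and with line 4 alone as the control it was 318. Leaving an arm with 1 array gave 28 calls without treated line 3, 129 without treated line 1, 149 without untreated line 1 and 123 without untreated line 3. Hoxa9, Hoxa10, Gfra1 and Ifitm3 were called in each of these. Lines 1 and 3 responded alike. Across genes, which are not independent replicates, their changes had a Pearson r of 0.939 and a Spearman rho of 0.820, and all 863 genes that moved by at least 1 in line 1 moved the same way in line 3.

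**Figure D2:**
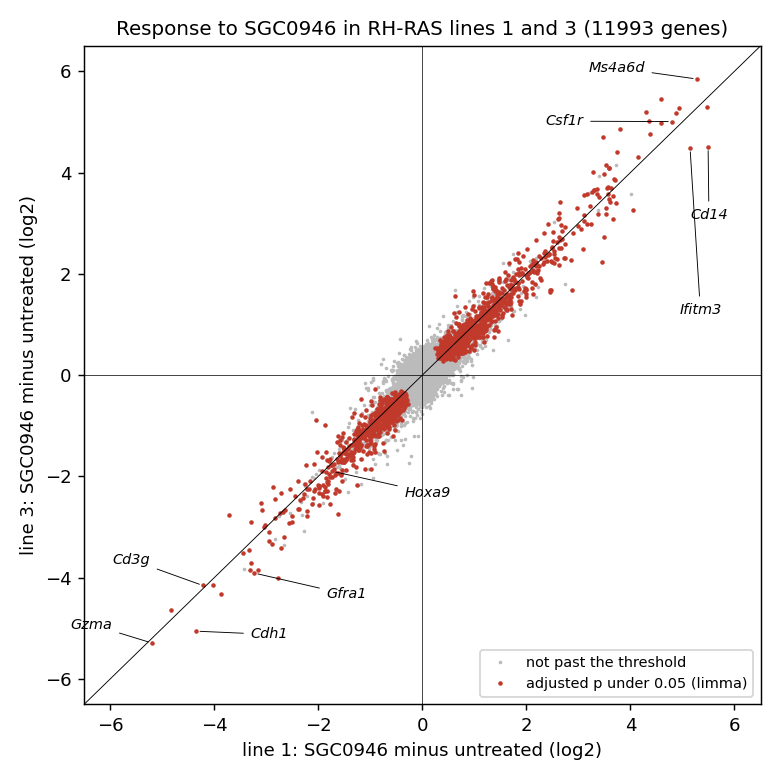
Log2 change under SGC0946 in line 1 (horizontal axis) and line 3 (vertical axis), 1 point per tested gene, with genes past the test coloured. All 1434 called genes had the same direction in both lines.

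The untreated RH-RAS lines were not equally alike. Lines 1 to 3 correlated with each other at r = 0.995 to 0.997 across genes, with 3 to 19 genes apart by more than 1 in any pair. Line 4 correlated with them at 0.986 to 0.988, with 225 to 255 genes apart. Line 4 minus line 2 correlated with the SGC0946 response of lines 1 and 3 at r = 0.648 (rho = 0.510), where line 2 minus lines 1 and 3 gave r = 0.0892. For 1092 of the 1434 called genes (76.2%), line 4 lay between lines 1 to 3 and both treated arrays. Gzma was at 7.91 in line 4 and at 10.0 to 10.5 in the other lines.

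The next comparison asks how RH-RAS lines differ from lines transformed by NUP98-JARID1A, a fusion of a nucleoporin with a histone demethylase. Granule and neutrophil genes were far higher in the 3 NUP98-JARID1A lines than in the 4 RH-RAS lines. Of 17 late neutrophil genes 15 were higher and 2 did not pass (median 4.97, camera adjusted p = 6.5e-06; adjusted p = 0.425 with an estimated correlation). The calprotectin subunits S100a9 and S100a8 were higher by 9.67 ± 0.38 and 9.23 ± 0.34 on the log2 scale (SE, limma adjusted p = 5.3e-06 and 5.1e-06), the iron-binding protein Lcn2 by 7.19 ± 0.79 (3.4e-04) and the granule protein Ngp by 6.91 ± 0.89 (6.8e-04). Of 12 primary granule genes 9 were higher and 3 did not pass (median 1.98, camera adjusted p = 0.00822; adjusted p = 0.425 with an estimated correlation), with Gstm1 at 6.09 ± 0.25, Ms4a3 at 5.08 ± 0.78 and the protease Ctsg at 5.06 ± 0.45. Both lists had the same counts when adjusted over the list alone.

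B lymphoid genes were lower as a list in NUP98-JARID1A lines. Among 9 members 5 were lower, 1 was higher and 3 did not pass, and 6 were lower and 1 higher when adjusted over the list alone (median −1.97, camera adjusted p = 0.00822; adjusted p = 0.425 with an estimated correlation). The recombinase genes Rag1 and Rag2 were at −7.00 ± 0.24 (adjusted p = 4.3e-06) and −3.87 ± 0.32, Dntt at −3.71 ± 0.35 and the interleukin receptor Il7r at −3.55 ± 0.64. Of 10 T and NK genes 5 were lower, 1 was higher and 4 did not pass, alike when adjusted over the list alone (median −0.47, camera adjusted p = 0.0778; 0.00766 without line 4). Gzma was at −5.26 ± 0.58, Cd3g at −3.67 ± 0.69 and Gata3 at 1.59 ± 0.21. Dendritic cell and MHC class II genes had 7 lower, 1 higher and 3 not past, alike when adjusted over the list alone (median −1.01, camera adjusted p = 0.00822, lost with each array's median subtracted; adjusted p = 0.425 with an estimated correlation). The MHC gene H2-Aa was at −2.32 ± 0.28 and the cytokine receptor Flt3 at −2.07 ± 0.25.

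RAS-MAPK feedback genes, which respond to signalling through RAS, were lower in the NUP98-JARID1A lines. Of 19 members 12 were lower, 2 were higher and 5 did not pass, alike when adjusted over the list alone (median −0.84, camera adjusted p = 0.00199; adjusted p = 0.425 with an estimated correlation). The pathway inhibitor Spry4 was at −4.25 ± 0.30 (adjusted p = 5.9e-05), Egr1 at −1.91 ± 0.49 and the cyclin Ccnd1 at −1.68 ± 0.27. Of 25 proliferation genes 14 were lower and 11 did not pass, with 14 lower and 1 higher when adjusted over the list alone (median −0.33, camera adjusted p = 2.3e-04; adjusted p = 0.425 with an estimated correlation). The nucleotide reductase Rrm2 was at −1.11 ± 0.15 and the mitotic kinase Bub1 at −0.94 ± 0.11. Of 16 cholesterol biosynthesis genes 10 were lower and 6 did not pass, alike when adjusted over the list alone (median −0.55, camera adjusted p = 4.2e-04; adjusted p = 0.439 with an estimated correlation), with Msmo1 at −1.46 ± 0.13 and Hmgcs1 at −1.25 ± 0.17.

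Amino acid and unfolded protein stress genes had 8 of 17 lower, 1 higher and 8 not past, alike when adjusted over the list alone (median −0.33, camera adjusted p = 0.00598; adjusted p = 0.425 with an estimated correlation). Ddit4 was at −2.33 ± 0.25 and Trib3 at −2.28 ± 0.26. Of 17 p53 targets and cell cycle inhibitors 7 were lower, 1 was higher and 9 did not pass, alike when adjusted over the list alone (median −0.22, camera adjusted p = 0.0128; adjusted p = 0.425 with an estimated correlation). Zmat3 was at −2.36 ± 0.37 and the cyclin-dependent kinase inhibitors Cdkn1a and Cdkn2c were at −1.29 ± 0.18 and 1.42 ± 0.12.

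The lists not called by camera included those of the Hox genes. In the Hoxa cluster 2 were higher, 2 lower and 3 not past, against 3 and 3 when adjusted over the list alone (median 0.31, mean −0.02, camera adjusted p = 0.571). Hoxa10 was lower by −1.15 ± 0.14 (adjusted p = 4.8e-04), while Hoxa9 at −0.31 ± 0.12 (0.0632), Hoxa7 at 0.31 ± 0.12 (0.0635) and Hoxa5 at 0.48 ± 0.26 (0.159) did not pass. The 3 measured Hoxb genes were higher, alike when adjusted over the list alone, with Hoxb5 at 2.03 ± 0.53, Hoxb3 at 1.54 ± 0.35 and Hoxb4 at 1.24 ± 0.17 (median 1.54, camera adjusted p = 0.127). Among 19 Hox cofactors and MLL-type targets 7 were higher, 7 lower and 5 not past, alike when adjusted over the list alone (median −0.02, mean 0.29, camera adjusted p = 0.332). Mn1, a transcriptional coactivator, was at −4.68 ± 0.29 (adjusted p = 3.6e-05), Eya1 at 4.29 ± 0.60, Mecom at 3.32 ± 0.68 and Pbx3 at 3.03 ± 0.56. Meis1 was at −0.02 ± 0.11 (adjusted p = 0.917), and the probe sets of Mycn were at −0.45, −4.73 and −1.19. Of 18 stem and progenitor genes 10 were higher, 2 lower and 6 not past, alike when adjusted over the list alone (median 0.75, camera adjusted p = 0.137), with the transcription factor Erg at 4.18 ± 0.17 and Prom1 at 2.96 ± 0.67.

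Monocyte and macrophage genes were mixed, with 10 of 20 higher, 4 lower and 6 not past, alike when adjusted over the list alone (median 1.44, camera adjusted p = 0.132; 0.0336 without line 4, where 13 were higher). The clotting factor F13a1 was at 6.55 ± 0.45 and Lyz2 at 4.76 ± 0.43. Of 8 mast cell and basophil genes 4 were higher and 4 not past, alike when adjusted over the list alone, with the protease Mcpt8 at 4.35 ± 0.57 and Mitf at 3.11 ± 0.25 (median 0.83, camera adjusted p = 0.332). In the erythroid list Car2 (−4.54 ± 0.30) and the erythropoietin receptor Epor (−0.37 ± 0.08) were lower and 3 did not pass, against 3 lower and 1 higher when adjusted over the list alone (median −0.37, camera adjusted p = 0.127). Of 10 megakaryocyte genes 5 were higher, 1 lower and 4 not past, alike when adjusted over the list alone, with Vwf at 3.72 ± 0.53 and F2r at −3.71 ± 0.24 (median 0.33, camera adjusted p = 0.448). Fibronectin Fn1 (3.74 ± 0.56) and the actin gene Acta2 (2.01-fold, SE 0.17 on the log2 scale) were higher in the fibroblast list and 3 members did not pass, alike when adjusted over the list alone (median 0.86, camera adjusted p = 0.192).

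Interferon-stimulated genes had 11 of 20 higher, 1 lower and 8 not past, against 11 and 2 when adjusted over the list alone (median 0.87, camera adjusted p = 0.127), with Oas1a at 2.35 ± 0.59 and Ifit2 at 2.00 ± 0.27. Of 16 inflammatory genes 8 were higher and 8 not past, alike when adjusted over the list alone, with Ccl9 at 4.72 ± 0.46 and the receptor antagonist Il1rn at 1.84 ± 0.37 (median 0.41, camera adjusted p = 0.0608; 0.0370 without line 4). MYC and ribosome biogenesis genes had 4 higher, 4 lower and 12 not past, alike when adjusted over the list alone, with the helicase Ddx21 at −1.40 ± 0.22 and Nop58 at −1.09 ± 0.15 (median 0.02, mean −0.08, camera adjusted p = 0.347). In the DOT1L complex and its partners 4 of 13 were lower, 1 higher and 8 not past, against 3 and 1 when adjusted over the list alone (median −0.10, camera adjusted p = 0.0778; 0.0438 with the array number as a block). Mllt3 was at −5.67 ± 0.40 (adjusted p = 6.0e-05), Aff3 at −2.14 ± 0.37 and Kmt2a at 1.32 ± 0.19. The probe set used for Dot1l was at −0.05 ± 0.11 (adjusted p = 0.748) and its other probe set at 1.07 ± 0.09. Of 11 DNA methylation enzymes and partners 3 were higher, 3 lower and 5 not past, against 4 and 3 when adjusted over the list alone (median −0.01, camera adjusted p = 0.555), with the demethylating dioxygenase Tet1 at −3.82 ± 0.36 and the methyltransferase cofactor Dnmt3l at 2.65 ± 0.36.

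**Figure D3:**
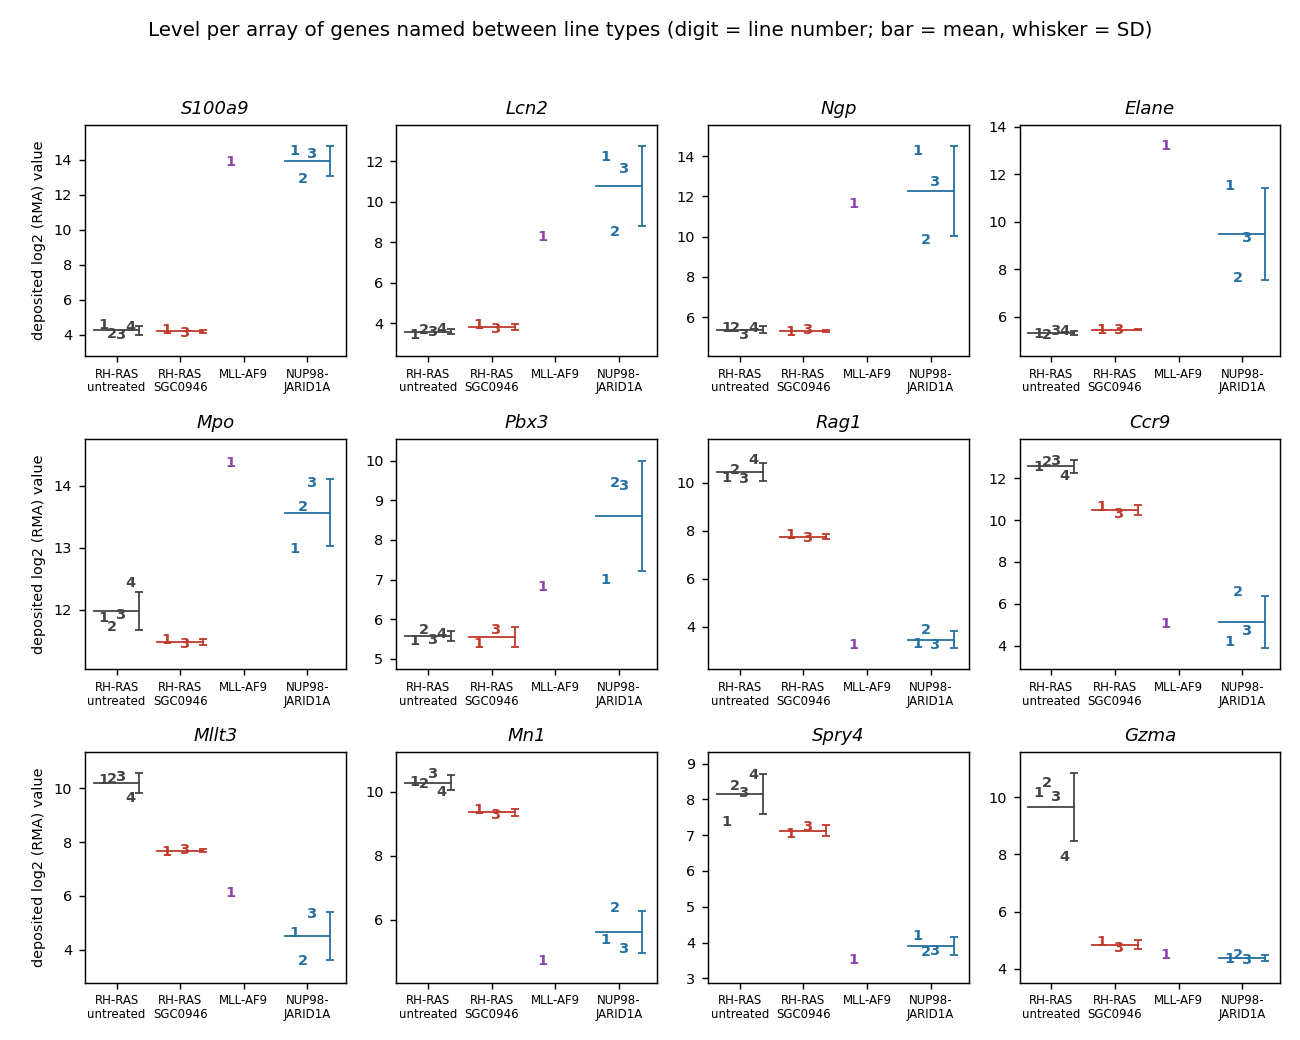
Log2 RMA intensity (vertical axis) of 12 genes on each array, by type of line. Digits are line numbers, bars are group means and whiskers are SD; the single MLL-AF9 array has none. S100a9 had a mean of 4.25 in RH-RAS lines and 13.9 in NUP98-JARID1A lines, and was at 13.9 in MLL-AF9.

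Across all genes, limma called 6113 of 11993 (51.0%), of which 3897 were higher and 2216 lower in NUP98-JARID1A lines. At least 2-fold differences numbered 1241 and 644. Of the called genes, 5902 had groups that did not overlap, and among all tested genes this share was 54.8%, where chance gives 5.71%. The other genes with the largest differences were Ifitm3 (8.35 ± 0.40), the glutathione transferase gene Mgst1 (7.71 ± 0.58), Stfa3 (7.21 ± 0.90) and Olfm4 (6.77 ± 0.84) above, and the chemokine receptor Ccr9 (−7.43 ± 0.53), Slc35d3 (−6.08 ± 0.27), the noncoding RNA Malat1 (−6.05 ± 0.31), the desmosome gene Dsp (−5.71 ± 0.41) and Trib2 (−5.32 ± 0.52) below. The RH-RAS means of Mgst1 (3.17), Stfa3 (3.32), Olfm4 (3.07), Lcn2 (3.58), S100a9 (4.25) and S100a8 (4.53) were near background. So were the NUP98-JARID1A means of Rag1 (3.45), Dsp (4.15), Slc35d3 (4.29), Trib2 (4.32), Gzma (4.38) and Mllt3 (4.51). The differences of these genes are understated, and the order of the genes is not exact. Probe sets of Malat1 ranged from −6.50 to 0.29. With each array's median subtracted, the median of all genes moved by −0.25, from 0.10 to −0.15, and 6650 genes were called, 2344 higher and 4306 lower. On that scale 21 proliferation genes, 12 p53 targets, 9 members of the DOT1L list and 8 MYC and ribosome genes were lower, and the median of the MYC list fell below 0. Without line 4 the count was 5724, and with the array number as a block it was 4938, although these numbers pair different lines (r from −0.0541 to 0.0703 between deviations with the same number).

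**Figure D4:**
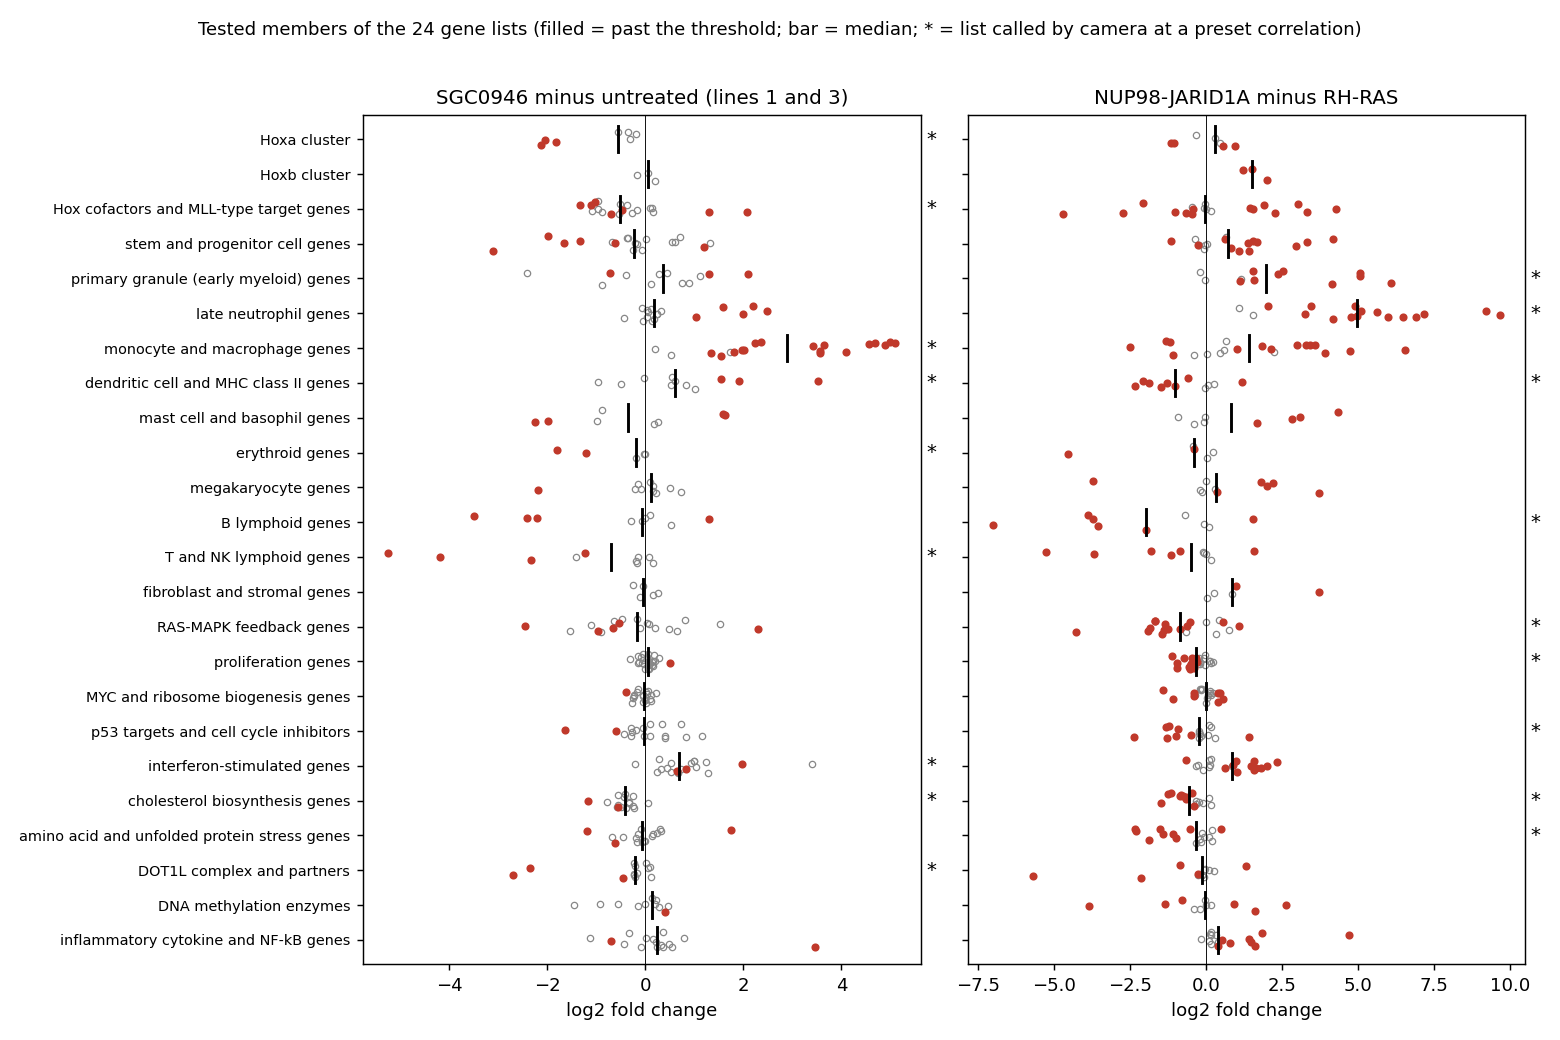
Log2 fold change of the tested members of each of the 24 gene lists (horizontal axis), for SGC0946 minus untreated in RH-RAS lines 1 and 3 and for NUP98-JARID1A minus RH-RAS lines. Points are genes, bars are medians and asterisks mark lists called by camera at the preset correlation of 0.01, 9 in each comparison.

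The last comparison sets the single MLL-AF9 array beside the 4 RH-RAS lines, without a test. Differences of at least 2 on the log2 scale, outside the range of the RH-RAS lines, numbered 314 above and 208 below. Outside that range by any amount lay 9074 of the 11993 tested genes. A count of list members outside it is therefore high for most sets of genes. Furthest above the RH-RAS mean were S100a9 (9.63), S100a8 (9.17), the neutrophil elastase gene Elane (7.85), Mgst1 (7.79), Gatm (7.60) and Ms4a3 (7.57). Furthest below were Ccr9 (−7.52), the cadherin gene Cdh17 (−7.31), Rag1 (−7.21), Mn1 (−5.57), Il18r1 (−5.36) and Gzma (−5.15). The RH-RAS means of Mgst1 (3.17), Gatm (3.13), S100a9 (4.25) and S100a8 (4.53) were near background, as were Rag1 (3.24), Gzma (4.50), Cdh17 (4.67), Mn1 (4.71) and Il18r1 (4.72) in MLL-AF9, so their differences are understated and the order of the genes is not exact. Late neutrophil genes had a median of 4.41 with 16 of 17 members above the RH-RAS range, and primary granule genes a median of 2.25 with 11 of 12 above, both at the 100th percentile of matched random lists. Medians at the 99.3th percentile or above were also those of monocyte (0.79), mast cell (1.19) and interferon genes (0.43). Medians at the 1.44th percentile or below were those of p53 target genes, with 13 of 17 members below the RH-RAS range, and of B lymphoid (−1.68), RAS-MAPK feedback (−0.93), dendritic cell (−0.76), cholesterol (−0.63), T and NK (−0.54), Hoxa (−0.48), erythroid (−0.40), proliferation (−0.23) and inflammatory genes (−0.21).

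Of the 19 RAS-MAPK feedback genes 15 were below the RH-RAS range in MLL-AF9, with Emp1 at −4.96, Spry4 at −4.65 and Etv5 at −3.85 from the mean. The other lists lay between the 8.33th and the 92.9th percentile, with medians of 0.29 for Hoxb, −0.10 for Hox cofactors, 0.03 for stem and progenitor, 0.12 for megakaryocyte, 0.33 for fibroblast, 0.18 for MYC and ribosome, 0.05 for amino acid stress, −0.15 for DOT1L complex and 0.04 for DNA methylation genes. Hoxa9 (−0.02), Hoxa7 (−0.14), Hoxa5 (−0.53) and Mycn (−0.10) were inside the RH-RAS range. Hoxa10 (−1.31), Meis1 (−0.36), Flt3 (−2.27), Pbx3 (1.23) and Dot1l (0.34) were outside it, as were 9074 of the 11993 tested genes. MLL-AF9 correlated with NUP98-JARID1A lines at r = 0.931 to 0.940 across genes and with untreated RH-RAS lines at 0.899 to 0.909.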

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

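The tests on untreated line 4 and on the rise of monocyte genes were chosen after the results were seen. The counts of other splits of the arrays were planned before.

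Among the 4 untreated RH-RAS lines, 1 line stood far from the other 3 for 8 of 45 named genes examined, by the gap to the nearest line as a share of the whole range, past Dixon's critical value for 4 samples. Line 4 was apart for Csf1r (share 0.931, log2 level 10.1), Mrc1 (0.926, 5.68), Mllt3 (0.878, 9.63), Ak4 (0.861, 7.96), Ms4a6d (0.860, 7.85), Selenbp1 (0.845, 7.76) and Hoxa9 (0.839, 12.4). Line 3 was apart for Ngp (0.915, 5.10). Chance gives about 1 in 20 such genes. Over all 11993 genes 856 (7.14%) had a line this far apart, and in 478 of them it was line 4, against 145 for line 1, 79 for line 2 and 154 for line 3.

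For 1092 of the 1434 called genes, line 4 lay part way from lines 1 to 3 toward the treated arrays, without inhibitor. RNA or cells of the treated cultures mixed into line 4 would need the same share for genes that rose and for genes that fell, which the tables argue against. Among genes that moved by at least 1 in both lines 1 and 3, chosen without line 4, the median share was 16.0% for 441 that rose (quartiles 6.86 and 30.6) and 60.9% for 287 that fell (37.2 and 80.3), 44.9 percentage points apart. Among called genes above a level of 6, where intensities are less compressed, the shares were 17.9 and 54.5%. A difference in the state of line 4, which the labels call independently derived, an array batch and a difference in culture or handling stay open and were not tested.

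Under SGC0946, 17 of 20 monocyte and macrophage genes rose, while 5 of 18 stem and progenitor genes fell and 1 rose. Macrophages that do not divide, mixed with leukemia cells that did not respond, are argued against by the proliferation list, none of whose genes is in the monocyte list. The falls of 3 or more would need a fall of about that size in it, and its median was 0.0527 (quartiles −0.05 and 0.13), while Lyz2, abundant in macrophages, went from 9.03 to a mean of 13.7. A batch that moved the treated arrays and line 4 by the same amount is argued against as the whole source. Both treated arrays lay beyond line 4 for 720 (98.9%) of the 728 genes that moved by at least 1 in both lines, chosen without line 4. A batch that moved line 4 less, or the treated arrays alone, is not covered by these values and was not tested. A change in the state of the leukemia cells is a candidate explanation, and a culture or handling difference between treated and untreated cultures, for which no vehicle is given, cannot be separated from the treatment and stays open.

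In the comparison of NUP98-JARID1A with RH-RAS lines, 1 of the 35 splits of the 7 arrays, the real one, gave 6113 genes, and the highest of the others gave 20. Every other split mixes the types of line, whose difference then adds to the spread, so low counts in them were built in. The gene counts of the splits therefore cannot exclude chance. For the count of gene lists, 8 of the 35 splits gave at least the 9 lists of the real one, and the highest other gave 12. The other splits divide the types of line unequally and so hold part of their difference. They are not a measure of chance, and the list counts neither exclude chance nor point to it.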

How the results depend on the processing

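The alternative with line 4 alone as the control was chosen after the data were seen, as was median subtraction for MLL-AF9 and for the correlation of lines 1 and 3. The count of genes changed by SGC0946 in RH-RAS lines, 1434, was 3708 with arrayWeights, 3746 with only the 4 arrays of lines 1 and 3 and 3229 with the line as a random block, and these 3 counts hold all 1434 genes. It was 844 with the line as a block, 318 with line 4 alone as control, 640 with a log2 change of at least 1 and 2200 at an adjusted p under 0.1. Other settings gave 1272 to 1878 genes, among them 1415 with medians subtracted, of which 49.6% were higher. Leaving out 1 array gave 28 to 1482 genes, with 28 without treated line 3, 129 without treated line 1, 149 without untreated line 1, 123 without untreated line 3 and 1482 without untreated line 2 or 4. An arm left with 1 array is assumed to vary like the other groups. Of the 20 named genes past the test 4, 6, 6, 6, 20 and 20 still passed in that order, and all 20 kept their direction. The thresholds and the smaller arms show their own cause. With only the 4 arrays of lines 1 and 3, the estimate of the spread leaves out lines 2 and 4 and the NUP98-JARID1A lines. The latter had 515 to 725 genes apart by more than 1, against 1 gene between the treated arrays. For the rest the cause was not tested.

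With an estimated correlation camera called 0 of 24 lists in both comparisons, where 3 lists under SGC0946 and 0 for NUP98-JARID1A had an unadjusted p under 0.05, against 9 and 9 at the preset correlation and 8 and 19 by fry, which does not compare a list with other genes. Under SGC0946 fry left out the interferon and cholesterol lists and added the stem and progenitor list, for which the cause was not tested. With an estimated correlation camera takes its degrees of freedom from the arrays of the fit, and at the preset from the genes. A list can then lose its call without a larger correlation. In the erythroid list under SGC0946 the estimate was −0.0806, below the preset, yet the unadjusted camera p rose from 0.0166 to 0.0585. Of genes different between NUP98-JARID1A and RH-RAS lines, 1885 had a log2 difference of at least 1, and the array number as a block gave 4938. An adjusted p under 0.1 gave 6998 genes, other settings gave 4539 to 6694, and leaving out 1 array gave 5121 to 5899, with all 20 named genes still past the test. With medians subtracted, 4560 of the 6113 genes were still called, all in the same direction. With the mean of probe sets 5053 were, of which 4963 kept their direction and the rest reversed. Of the named genes, Dot1l reversed to 0.51 with the mean of its probe sets, which combines probe sets at −0.05 and 1.07. Of the other values of named genes under alternatives, 248 were the same, and 10 passed the test anew for NUP98-JARID1A. Under SGC0946 these were 290 and 15, and 5 no longer passed. For MLL-AF9 against RH-RAS and NUP98-JARID1A lines the count stayed between 391 and 553. Low intensities are compressed, which limits fold changes near background.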

Other observations

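The test of the hypothesis here, like the genes of the next paragraph, was chosen after values had been seen. It replaced a correlation planned before the results were seen, in which both differences are taken from RH-RAS lines that are nearly alike. Such a correlation is above 0 even for unrelated profiles, so it is given as a value and decides nothing.

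Xist, the RNA of the inactive X chromosome, was at 13.3 to 13.5 in untreated RH-RAS lines 1 to 3, 12.5 in line 4, 12.4 and 12.5 in the treated arrays, 12.9 in MLL-AF9 and 10.4 to 11.2 in NUP98-JARID1A lines. The Y-linked genes Eif2s3y and Uty were near background on every array (2.76 to 3.16 and 3.70 to 4.09). The germ cell helicase Ddx4 was at 9.83 in line 4 and at a mean of 7.14 ± 0.18 (SD, n = 3) in lines 1 to 3, but at 4.23 and 3.77 in the treated arrays, so that here line 4 lay away from them (SGC0946 change −3.04 ± 0.89, adjusted p = 0.0694). Of the mouse genes that correspond to the driving lesions, Dnmt3a differed by −0.37 ± 0.22 (adjusted p = 0.207), Nras by −0.36 ± 0.09 (0.0135), Nup98 by 0.11 ± 0.10 (0.376), and Kdm5a, which encodes JARID1A, by −0.89 ± 0.14 (0.00185) between NUP98-JARID1A and RH-RAS lines in the limma fit. Whether these probe sets detect the transforming sequences was not tested, so the values need not be levels of the drivers. Mllt3, the partner gene of MLL in MLL-AF9, had a mean of 10.2 in untreated RH-RAS lines, 7.68 in treated lines and 4.51 in NUP98-JARID1A lines, and was at 6.09 in MLL-AF9.

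A hypothesis was that SGC0946 moves RH-RAS lines toward the NUP98-JARID1A profile. A shift of the treated lines that is unrelated to that profile would increase their distance from it. In 6 of 6 pairs of a treated and a NUP98-JARID1A array the treated array was nearer than the untreated array of its line, with root mean square log2 differences of 0.902 to 1.03 against 0.951 to 1.14. These pairs share 2 treated arrays, which correlated with each other at r = 0.997, so the pairs are not independent. The correlation of levels with NUP98-JARID1A arrays was 0.883 to 0.909 in treated and 0.858 to 0.899 in untreated arrays of these lines. With MLL-AF9 it was 0.906 and 0.904 against 0.902 and 0.899. Untreated line 4 was at 0.909 with MLL-AF9, above both treated arrays. With NUP98-JARID1A arrays 1, 2 and 3 it was at 0.878, 0.901 and 0.867, above untreated lines 1 to 3 and below the treated arrays. A nearer profile was thus also seen without inhibitor. The planned correlation, of the response of lines 1 and 3 with NUP98-JARID1A minus line 2, was r = 0.409 (rho = 0.351), and r = 0.311 with lines 2 and 4 as the reference. The distances may reflect a partial shift toward NUP98-JARID1A lines or a loss of expression particular to RH-RAS lines, and the 4 arrays of lines 1 and 3 cannot tie either to a cause.

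MLL-AF9 minus lines 1 and 2 correlated across genes with NUP98-JARID1A minus lines 3 and 4 at r = 0.714 (rho = 0.545), and at 0.727 with the pairs of RH-RAS lines exchanged. Because the reference lines are nearly alike, this does not show that MLL-AF9 and NUP98-JARID1A lines share changes.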
